A study of Mus musculus with 4 samples.

How the data were processed

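Single-cell RNA was measured in 4 libraries of mouse heart cells 1 week after myocardial infarction, 1 library per group: Ctrl, CKO, CKO untreated and CKO cilengitide. Per the labels' protocols, hearts were digested with liberase, live cells were sorted with calcein AM at 10 µM, and 3′ libraries were made with the 10x Genomics Chromium kit. Per the submitters' processing notes, reads were processed with Cell Ranger on mm10, with no version given. The deposited files came as 2 tables of 2 libraries each, with a sample and a cell type for every cell in companion files. How many animals entered a library, and how the authors filtered cells or removed doublets, is not given in the sources used here.

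The deposited tables are named raw counts but hold natural log values, which the authors made as ln(1 + UMIs per 10000 UMIs of the cell), judging from the values. Raised back, the values summed to 10000 in every cell, and 100% of 33759106 and 50066417 nonzero values were whole UMIs within 0.01 UMI, in 17826 cells by 21443 genes and 18545 cells by 21901 genes. Those whole UMIs were used throughout, and 20366 genes were in both tables. The design, fixed before the data were examined, had assumed that the tables hold counts, and its summed UMIs could be computed as written. Every barcode of the tables had a sample and a cell type from the authors. The untreated CKO libraries of the tables shared 13 barcodes and were treated as separate libraries.

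UMIs were summed per library and cell class and given as CPM of the class's total with exact Poisson intervals. Ratios between libraries were given as log2 with 0.5 counts added and an exact conditional interval. Shares of cells had Clopper-Pearson intervals, all at the 95% level and for counting error only. A count of 0 was given a floor of 3 counts. Genes with at least 50 UMIs over both libraries of a class counted as measured. Fibroblasts were described first, with macrophages and endothelial cells as the other large classes with enough cells. Shares of cells with a UMI were taken after each cell was thinned to 2000 UMIs. Fibroblasts with fewer UMIs were left out, 161 in Ctrl, 189 in CKO, 53 in CKO untreated and 136 in CKO cilengitide.

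Named genes followed a rule fixed before the data were examined: per comparison the 12 highest and 12 lowest in fibroblasts, and 6 each way in the other classes, ranked by the interval bound nearest to no change. Mitochondrial, ribosomal, haemoglobin, sex-linked, immunoglobulin and predicted genes were left out of that ranking, as were genes whose level was under 0.1 of that in another class. Always named were Col5a1, Col5a2, Col5a3, Col1a1, Col1a2, Col3a1, Acta2, Postn and the integrin genes Itgav, Itgb3, Itgb5 and Itgb1, with up to 4 members per gene list. The 24 gene lists, fixed at the same time, covered fibrillar collagens, other collagens, matrix proteins, collagen processing, contractile genes, integrins, focal adhesion, YAP and SRF targets, TGF-beta, matrix proteases, late scar, resting fibroblasts, cytokines, interferon, cell cycle, glycolysis, oxidative phosphorylation, endoplasmic reticulum folding, immediate early stress, class II, resident macrophages, recruited monocytes, phagocytic genes and angiogenesis. A list was described by its median log2 ratio and by the percentile of that median among 10000 random lists of equal size drawn within 20 bins of expression. With 1 library per group no test between groups was run.

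Cells were split into Xist-only and Y-only cells by UMIs of Xist and of Ddx3y, Eif2s3y, Uty and Kdm5d. Own clusters used 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, and a leading gene had to be detected in at least 10% of a cluster's cells, a limit set after the clusters had been seen. Own classes matched the deposited ones for 90.8% of cells in the first table and 96.7% in the second, where epicardial cells of the own clusters lay among the deposited fibroblasts. Scrublet marked 81 cells in Ctrl, 4 in CKO, 216 in CKO untreated and 444 in CKO cilengitide, and no cells were removed in the main values.

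Alternatives were other scalings (trimmed mean of M values, median of ratios and a total without the 50 most abundant genes), an equal weight per cell, thinned cells, minimums of 200 and 1 UMI, 5 counts added, cells with at least 500 genes and under 10% mitochondrial UMIs, removal of doublets, own classes and the exchange of the untreated knockout libraries. Cells at 10% mitochondrial UMIs or more numbered 463 in Ctrl and 913 in CKO and 0 in the second table. The ratio step was tested on simulated Poisson sums with 200 changed genes. The intervals assume that same model, so their coverage checks the computation and not the spread between cells or animals. Intervals covered 95.6% of unchanged genes among 11842 for CKO over Ctrl in fibroblasts, and 95.3% among 13485 for cilengitide over untreated. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and coordinates from GENCODE M21 on GRCm38, the assembly also called mm10.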

Results

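Gene expression was measured in single cells from mouse hearts 1 week after myocardial infarction, in 4 libraries with 1 library per group. The first table held a wild-type library (Ctrl, 6857 cells, 39.7 M UMIs, median 5091 UMIs per cell) and a Col5a1 knockout library (CKO, 10969 cells, 61.5 M UMIs, median 5012). The second table held a knockout library without drug (CKO untreated, 6790 cells, 81.6 M UMIs, median 10471.5) and a knockout library from cilengitide treatment (CKO cilengitide, 11755 cells, 111.7 M UMIs, median 7933). Col5a1 encodes a chain of type V collagen, a minor fibrillar collagen that helps set the width of collagen fibrils. Cilengitide is a cyclic peptide that blocks the integrins αvβ3 and αvβ5, which are receptors for matrix proteins on the cell surface. Going by the title and design text, the first comparison asked how cells of the healing heart differ when Col5a1 is lost, and the second how knockout hearts differ under an integrin blocker. Because each comparison had 1 library per group, no test between groups was run. The 2 untreated knockout libraries lay in different tables, so their difference may come from the table as well as from the animals. That difference was wider than either comparison. Over measured fibroblast genes its log2 ratios had a standard deviation of 0.58, counting error included. The value was 0.35 for CKO over Ctrl and 0.42 for cilengitide over untreated, each within 1 table. In macrophages these values were 0.54, 0.37 and 0.44. Each difference describes the libraries compared, and each 95% interval covers counting error only.

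Transcripts of the sex chromosomes showed cells of both sexes in some libraries but not in others. Cells with a UMI of Xist and none of 4 Y-linked genes (Xist-only cells) numbered 3427 in Ctrl, 7017 in CKO, 6459 in CKO untreated and 3400 in CKO cilengitide. Cells with a Y-linked UMI and none of Xist (Y-only cells) numbered 1240, 1220, 0 and 4601. Many values of the CKO and Ctrl comparison are therefore also given within both kinds of cells, and many of the cilengitide comparison within Xist-only cells, since CKO untreated had no Y-only cells. This split was chosen after the data had been seen. Cells with neither Xist nor a Y-linked UMI made up 30.8% of Ctrl, 22.9% of CKO, 4.79% of CKO untreated and 28.6% of CKO cilengitide. Values within the split therefore also depend on depth and on detection of these genes. Xist-only and Y-only cells also come from different animals, so sex and animal cannot be told apart. In brackets, the value over all cells comes first, then that of Xist-only cells, then that of Y-only cells where there were any.

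Col5a1 itself was lower in knockout fibroblasts, at 253 CPM (95% Poisson interval 245 to 260) in CKO against 928 (913 to 944) in Ctrl, a level 3.68-fold lower (3.55 to 3.80). The log2 ratio of CKO over Ctrl was -1.88 over all fibroblasts, -1.86 in Xist-only cells and -1.71 in Y-only cells. Fibroblasts of the other knockout libraries held 302 CPM (CKO untreated) and 377 CPM (CKO cilengitide). Once every cell was thinned to 2000 UMIs, 29.0% of CKO fibroblasts (545 cells, Clopper-Pearson interval 26.9 to 31.1%) held a Col5a1 UMI, against 80.2% (78.2 to 82.1%) in Ctrl. Without thinning the shares were 51.5% and 93.8%, and in macrophages, which should lack the gene, the thinned shares were 0.640% and 0.775%, at median depths of 4892 and 4921.5 UMIs against 8584 and 8215 in fibroblasts. Col5a1 lies on chromosome 2 at 27886425 to 28039514 of GRCm38 (ENSMUSG00000026837.15). The deleted exons are not given in the sources used here, and 3′ tags can lie outside them, so the level that remains does not measure intact transcript.

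Outside Col5a1, knockout fibroblasts carried more contractile transcripts and fewer transcripts of resting fibroblasts, while most fibrillar collagens stayed near their Ctrl level. Acta2, the smooth muscle actin that marks myofibroblasts, stood at 1345 CPM in CKO and 858 in Ctrl (log2 ratio 0.65, interval 0.62 to 0.68), with 0.84 in Xist-only and 0.36 in Y-only cells. A UMI of Acta2 was seen in 55.9% of thinned CKO fibroblasts (53.6 to 58.2%) and 40.1% of Ctrl fibroblasts (37.7 to 42.5%), against 4.70% and 1.85% in macrophages. The unthinned shares in fibroblasts were 73.5% and 59.3%. Postn, the matricellular protein periostin, was at 4913 against 4585 CPM, and its log2 ratio of 0.10 became -0.068 in Xist-only and 0.61 in Y-only cells. Among the partners of the missing chain, Col5a2 was slightly higher (log2 ratio 0.17, 0.17 Xist-only, 0.25 Y-only) and Col5a3 lower (-0.31, -0.46 and -0.79). The major fibrillar collagens Col1a1, Col1a2 and Col3a1 had log2 ratios of -0.11, -0.033 and -0.25 over all fibroblasts. Those became -0.17, -0.085 and -0.36 in Xist-only cells but 0.15, 0.19 and 0.040 in Y-only cells, so no direction held in both. Of the integrin subunits, Itgb5 (0.14, 0.23 and 0.014) was a little higher. Itgb1 (0.16, 0.22 and 0.036) was too, but with CKO untreated in place of CKO its log2 ratio to Ctrl was -0.52. Itgav (-0.036, 0.13 and -0.35) went opposite ways in the kinds of cells and the interval of Itgb3 (0.27, interval -0.13 to 0.67) included 0.

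**Figure D1:**
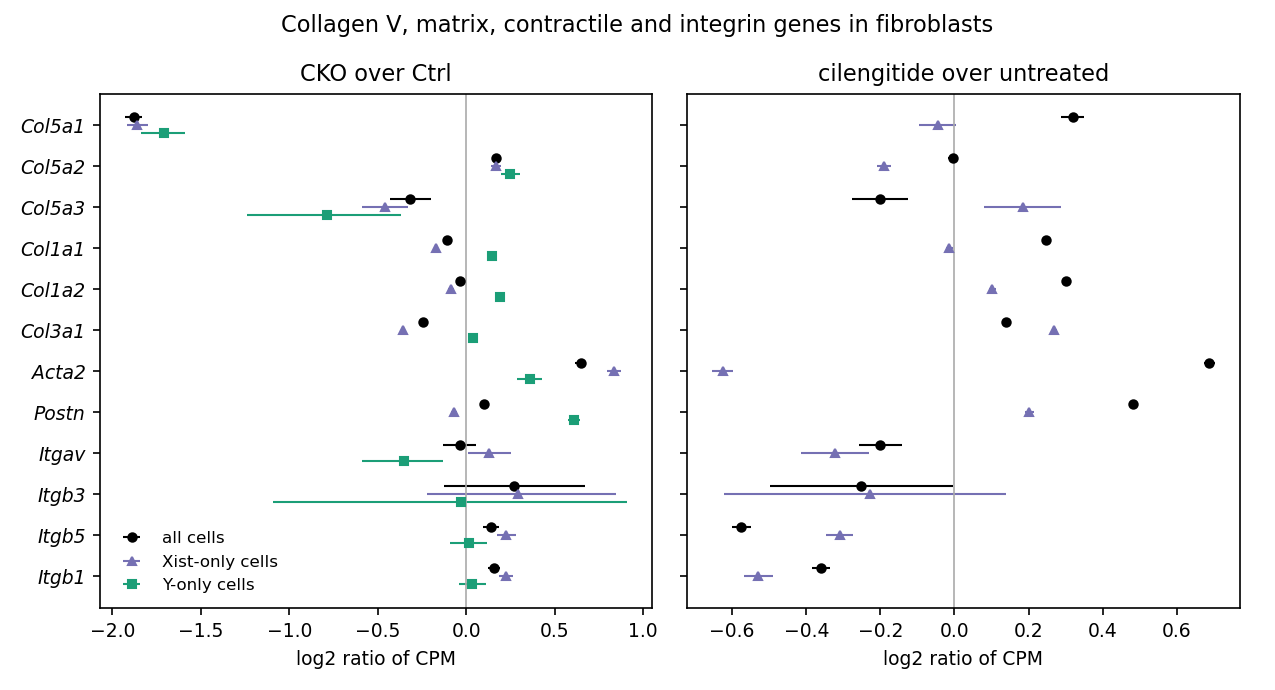
Log2 ratio of CPM in fibroblasts (x axis) for 12 genes named before the data were examined (y axis), CKO over Ctrl on the left and cilengitide over untreated on the right. Circles are all cells, triangles Xist-only cells and squares Y-only cells, with 95% counting intervals. Col5a1 lies at -1.88, -1.86 and -1.71 on the left, while Acta2 lies at 0.69 and -0.62 on the right.

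The gene lists fixed in advance showed which programmes these genes belong to. Of 36 measured contractile and myofibroblast genes, 34 lay above 0 in CKO (median log2 ratio 0.23), led by Actg2 (1.20), Cnn1 (1.01), Acta2 and Tagln (0.48). The median sat at percentile 100 of 10000 random lists matched on expression, and was 0.35 in Xist-only and 0.16 in Y-only cells. The 11 mural cell markers, some of which are contractile genes themselves, were also higher, at 0.0292% of fibroblast UMIs in CKO (0.0284 to 0.0300%) against 0.0252% in Ctrl (0.0244 to 0.0260%), so RNA of smooth muscle cells may have a part in this. Of 25 resting fibroblast genes, 22 lay below 0 (median -0.37, -0.32 and -0.35), including Scara5 (-1.35), Clec3b (-0.98), Fbln1 (-0.77) and Gsn (-0.68). Metabolic lists were higher over all fibroblasts and in Xist-only cells but close to 0 in Y-only cells. For oxidative phosphorylation the medians were 0.18, 0.27 and -0.0013 (45 of 46 genes above 0 over all cells, Atp5k at 0.50), and for glycolysis and hypoxia 0.20, 0.23 and 0.057 (24 of 32, Gapdh at 0.47). Collagen processing and crosslinking genes were higher by a small margin in both (median 0.10, 0.16 and 0.075), with 22 of 29 above 0, among them Loxl2 at 0.36 and Plod3 at 0.30.

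Matrix lists had opposite signs in Xist-only and Y-only cells, which come from different animals. Fibrillar collagens other than Col5a1 had a median of -0.033 over 9 genes (-0.17 Xist-only, 0.17 Y-only), other collagens -0.037 over 22 genes (-0.10 and 0.072, Col4a3 at -0.98, Col8a1 at 0.41), and non-collagen matrix proteins -0.053 over 51 genes (-0.10 and 0.092, and 0.12 with CKO untreated in place of CKO). Within the latter, Tnxb (-1.14), Spon2 (-0.85) and Fbln1 were lower and Tnc, the tenascin C of wound matrix, was higher (0.66). Late scar genes, typical of matrifibrocytes, went from -0.12 in Xist-only to 0.26 in Y-only cells around -0.051 over all cells (Cilp2 at -1.21), and to 0.28 with CKO untreated in place of CKO. The cell cycle list parted most, with 0.27 over all fibroblasts (39 of 44 genes above 0, Mki67 at 0.71, Top2a at 0.61), 0.76 in Xist-only and -1.15 in Y-only cells. Few cells carry these values. In thinned fibroblasts Mki67 was seen in 2.92% of CKO (2.21 to 3.79%) and 2.07% of Ctrl cells (1.44 to 2.88%). Top2a was seen in 2.02% (1.43 to 2.76%) and 1.64% (1.09 to 2.38%). The Y-only fibroblasts numbered 229 in CKO and 384 in Ctrl. Interferon response genes had medians of 0.016, -0.12 and 0.25 (Oas3 at 1.58). Integrin subunits (0.14, 0.23 and 0.070) included the leukocyte genes Itgam (1.68), Itgax (1.85) and Itgb2 (1.48), and their median was 0.077 without members whose level was under 0.1 of that in another class and 0.0021 with CKO untreated in place of CKO. Focal adhesion genes reached 0.10 (0.15 and 0.013, Cav1 at 0.70, Zyx at 0.36). Smaller medians were found for YAP and SRF targets (0.057, 0.073 and 0.047, Ankrd1 at 0.72, Igfbp3 at -0.77), TGF-beta genes (-0.10, -0.060 and -0.078, Nrros at 1.36), matrix proteases and inhibitors (-0.10, -0.0021 and -0.12, Mmp9 at 3.27, Mmp3 at -1.52), endoplasmic reticulum folding (0.10, 0.17 and 0.0071, Sdf2l1 at 0.41) and immediate early stress genes (-0.035, -0.051 and -0.086, Nfkbia at -0.34). With CKO untreated in place of CKO the TGF-beta median was 0.031 and that of endoplasmic reticulum folding -0.035.

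Lists of leukocyte genes were also higher in CKO fibroblasts. Alongside them, macrophage markers made up 0.499% of fibroblast UMIs in CKO against 0.330% in Ctrl. Class II antigen presentation genes had a median of 0.85 (1.32 and 0.42), which was -0.54 with CKO untreated in place of CKO. Medians were also above 0 for resident macrophage genes (0.39, 0.19 and 0.14, Ccl24 at 2.64), recruited monocyte genes (0.32, 0.39 and 0.023, F10 at 3.65) and phagocytic genes (0.25, 0.27 and 0.053, Arg1 at 2.37). Ccl24, F10 and Arg1 were all leading genes of 1 own cluster, with 1030 macrophages of CKO and 129 of Ctrl. They need not mark separate programmes. Inflammatory cytokines stood at 0.20 (0.27 and -0.13, Ccl4 at 1.58), but at -0.038 without members whose level was under 0.1 of that in another class, and angiogenesis genes at 0.12 (0.14 and -0.12, Esm1 at -1.55).

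The fibroblast genes farthest above Ctrl were Gpt2, a mitochondrial alanine aminotransferase, at 64.3 against 2.28 CPM (27.8-fold, 20 to 40.9), and Prm1, a sperm protamine, at 9.28 against 0.269 CPM (30.8-fold, 13.2 to 128, from 165 and 4 UMIs). Both stood out in Xist-only (log2 ratios 4.88 and 4.85) and Y-only cells (5.07 and 4.90, Prm1 from 22 against 1 UMIs) and in every knockout library: CKO untreated fibroblasts held 59.3 and 9.32 CPM, and CKO cilengitide fibroblasts 56.1 and 10.0 CPM. Gpt2 lies on chromosome 8 at 85492576 to 85527560 and Prm1 on chromosome 16 at 10796326 to 10805839 of GRCm38. Next came Wfdc18 (1511 against 317 UMIs), the growth factor binding protein Igfbp2 (log2 ratio 1.73), the hyaluronan-degrading Cemip (1.32), the glutamate transporter Slc1a6 (1.38) and Plekha7 (1.07), all higher in both kinds of cells, Plekha7 from 19 against 15 UMIs in Y-only cells. Ptprz1 (1.88), Cd200r1 (1.55), Scg2 (1.40), Shroom3 (1.49) and Pdlim4 (1.01) completed the 12, each from 226 UMIs or fewer in CKO, and Pdlim4 was at -1.86 in Y-only cells (4 against 32 UMIs). For Wfdc18 56.8% of the CKO UMIs came from 10 cells, and for Igfbp2 68.0%.

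**Figure D2:**
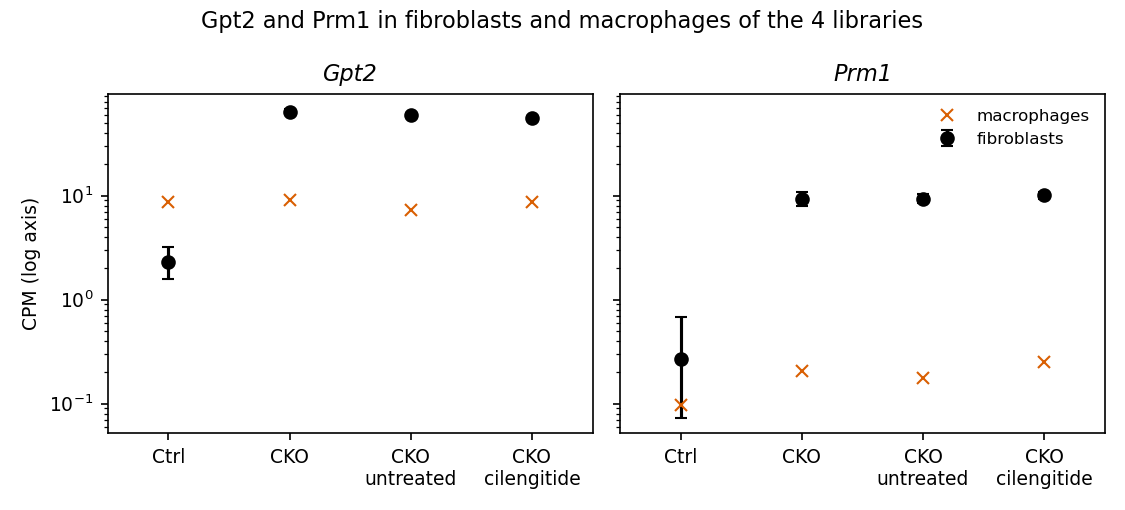
CPM on a log axis for Gpt2 and Prm1 in the 4 libraries (x axis). Circles are fibroblasts with 95% Poisson intervals and crosses are macrophages. Fibroblast Gpt2 lies at 2.28 in Ctrl and between 56.1 and 64.3 in the knockout libraries.

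The fibroblast genes farthest below Ctrl after Col5a1 were the chemokine Cxcl14 (log2 ratio -1.82, -0.80 Xist-only, -1.79 Y-only), Lsamp (-1.93), the stromelysin Mmp3 (-1.52), Tmem100 (-1.57), the carbonic anhydrase Car3 (-1.84), Wfdc12 (-1.67), tenascin X (Tnxb, -1.14), Gipc2 (-1.78), Clec3b (tetranectin, -0.98), Slco1c1 (-1.73) and Igfbp6 (-0.92). Each was below 0 in Xist-only and Y-only cells alike, but Lsamp, Tmem100, Car3, Wfdc12, Gipc2 and Slco1c1 had too few UMIs in Y-only cells to count as measured there, and Car3, Gipc2 and Slco1c1 also in Xist-only cells. Mmp3 was the exception among libraries: with CKO untreated in place of CKO its log2 ratio to Ctrl was 0.21. Car3, Gipc2 and Slco1c1 rested on 17, 15 and 13 UMIs in CKO.

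Macrophages, the largest class, held more RNA of a few secreted and granule proteins as a class in CKO, and more matrix transcripts. The proteinase 3 gene Prtn3 stood at 105 against 15.5 CPM (6.76-fold, 6.04 to 7.61), Prg4, which encodes lubricin, at 60.7 against 8.89 CPM (6.81-fold, 5.87 to 7.97), and Clmn at 11.7 against 1.25 CPM (9.21-fold, 6.31 to 14.5). Gprc5b (2.72) and Naip1 (2.57) had similar log2 ratios. Prtn3, Prg4 and Clmn were at 3.03, 3.63 and 3.44 in Xist-only cells, and Prtn3 at 0.86 in Y-only cells, where Prg4 (13 against 30 UMIs) and Clmn (7 against 1) were too sparse to count as measured. With classes from own clusters Prtn3 was at -0.54 and Prg4 at 2.68, since a cluster led by Saa3, Arg1 and Prtn3, with 1030 macrophages of CKO and 129 of Ctrl, then left the class. The Prtn3 difference therefore rests on the cells of that cluster, while that of Prg4 does not rest on them alone. Mt3 was at least 9.50-fold higher against the floor of 3 counts, but its 53 UMIs came from 4 cells. Lower in CKO were Elane (2 UMIs against 48, from 2 cells each), the iron-recycling regulator Spic (-1.26), Bcl2a1c (-1.41), the stress cytokine Gdf15 (-0.90, -1.17 and -0.19), Pdpn (-0.81) and Slc25a33 (-0.78). All but Elane and Bcl2a1c, too sparse in Y-only cells, lay below 0 in both kinds of cells, but Pdpn was at 0.15 with CKO untreated in place of CKO.

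Matrix lists were higher in CKO macrophages in both kinds of cells. Their medians were 0.87 for fibrillar collagens (0.69 and 0.97, Col5a2 at 1.72), 1.04 for other collagens (0.66 and 1.01) and 0.88 for non-collagen matrix proteins (0.69 and 0.80, Fn1 at 1.56, Postn at 1.45). The 13 fibroblast markers made up 0.0603% of macrophage UMIs in CKO and 0.0430% in Ctrl, and most matrix genes lay far below their fibroblast level. Recruited monocyte genes were higher (0.18, 0.36 and 0.11), and resident macrophage genes (-0.18, -0.16 and -0.24) and phagocytic genes (-0.13, -0.20 and -0.037, Il10 at -0.75) were lower, though the resident genes Fcna (1.72), Timd4 (1.91) and Cd163 (1.29) went the other way. Fcna was also a leading gene of the cluster led by Saa3, Arg1 and Prtn3, with 1030 macrophages of CKO and 129 of Ctrl. Its ratio may therefore rest on that cluster. With classes from own clusters the recruited monocyte median was -0.049, and with CKO untreated in place of CKO the phagocytic median was 0.16. Interferon response genes had 0.028 over all macrophages, -0.21 in Xist-only and 0.39 in Y-only cells.

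In endothelial cells of CKO the cell cycle list was lower, with 30 of 34 genes below 0 (median -0.50, -0.36 Xist-only, -1.41 Y-only, Cenpf at -1.31, Birc5 at -1.30). The class held 506 cells in CKO and 485 in Ctrl, with 45 Y-only cells in each. An own cluster of endothelial cells led by Hist1h1b and Top2a held 17 cells over both libraries, so few cells may carry these values. Interferon response genes had a median of -0.25 (-0.49 and 0.37). Timp4, an inhibitor of matrix proteases (log2 ratio -2.34), Clic5 (-1.38), Sh3rf1 (-1.93), Igfbp5 (-1.12) and the mitotic gene Hmmr (-1.69) were lower, as was Car2 (-1.67), whose 86 Ctrl UMIs came from 6 cells. Neurotensin (Nts, 1.36), the chemokine Ccl2 (1.43), neuregulin (Nrg1, 1.16), Ephx2 (1.45) and the heme oxygenase Hmox1 (0.97) were higher. For Nts, Ccl2, Nrg1, Ephx2 and Hmox1 over 60% of the CKO UMIs lay in 10 cells, and with CKO untreated in place of CKO the log2 ratios of Nts, Ccl2 and Nrg1 were -0.74, -0.68 and -0.99, with Ephx2 too sparse to count as measured. Macrophage markers made up 0.736% of endothelial UMIs in CKO against 0.561% in Ctrl, and fibroblast markers 0.158% against 0.0941%. Erythroid markers made up 0.0390% against 0.000212%, and neutrophil markers 0.0215% against 0.00611%. Hmox1 was at -0.56 in Xist-only cells (interval -1.02 to -0.10). Most of these genes were too sparse in Y-only cells to count as measured.

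Cell composition differed between CKO and Ctrl. Macrophages made up 68.4% of CKO cells (Clopper-Pearson interval 67.5 to 69.2%) and 57.5% of Ctrl cells (56.3 to 58.7%), fibroblasts 18.9% (18.1 to 19.6%) against 26.3% (25.3 to 27.4%), and endothelial cells 4.61% against 7.07%. Smooth muscle cells were 0.875% against 1.30% and B cells 0.547% against 0.846%, while neutrophils (3.43% against 3.15%), T cells (1.63% against 1.78%), dendritic cells (1.32% against 1.53%) and epithelial cells (0.337% against 0.525%) had difference intervals that included 0. The T cell difference of -0.147 points was nonetheless -1.12 in Xist-only cells, 1.73 in Y-only cells and -1.38 with CKO untreated in place of CKO, the neutrophil difference of 0.278 was -2.06 with that exchange, and the dendritic and epithelial differences of -0.209 and -0.188 were -0.705 and -0.886 in Y-only cells. The macrophage difference of 10.9 points was 15.5 in Xist-only and 12.2 in Y-only cells, but 2.59 with classes from own clusters and -6.63 with CKO untreated in place of CKO. The fibroblast difference of -7.44 points was -9.56 in Xist-only and -12.2 in Y-only cells, but with that exchange it was 13.6. The endothelial difference of -2.46 points was -4.55 in Xist-only cells, 0.0595 in Y-only cells and -0.784 with the exchange. The B cell difference of -0.299 points was 0.10 in Y-only cells, 0.0748 with own classes and -0.743 with the exchange. The smooth muscle difference was 0.0275 with the exchange. A live-cell sort and enzymatic digestion also set these shares.

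**Figure D3:**
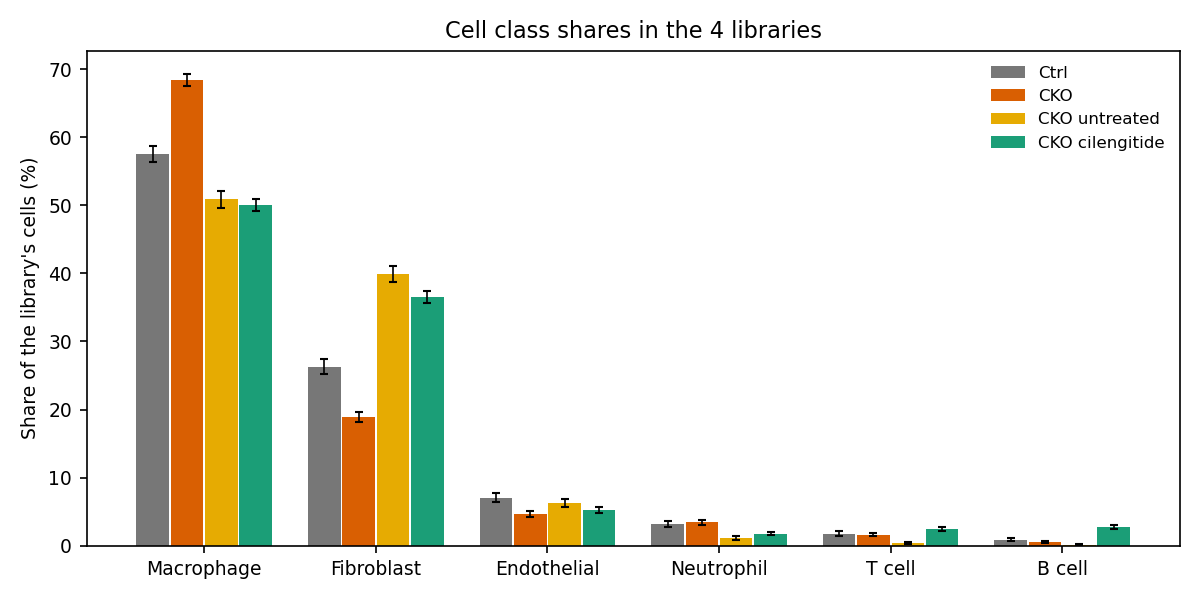
Share of each library's cells (y axis, percent) in 6 cell classes of the deposited annotation (x axis), with 95% Clopper-Pearson intervals for counting error. The fibroblast bars stand at 26.3, 18.9, 39.9 and 36.5%, so that the 2 untreated knockout libraries lie on opposite sides of Ctrl.

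With cilengitide, knockout fibroblasts carried less RNA of the β1, β5 and αv integrin subunits and of YAP and SRF target genes. They carried more of the matrix genes Tnc and Postn. Itgb5 stood at 429 CPM against 639 in CKO untreated (log2 ratio -0.58, interval -0.60 to -0.55, -0.31 in Xist-only cells), Itgb1 at 494 against 635 (-0.36, -0.53) and Itgav at 91.7 against 105 (-0.20, -0.32). Itgb3, at 5.16 against 6.14 CPM (-0.25, interval -0.50 to -0.0029, -0.23), was lower on few UMIs, with an interval that nearly reached 0. Of 24 measured YAP and SRF target genes, 19 lay below 0 (median -0.23, -0.20 in Xist-only cells), including Dlc1 (-0.63), Crim1 (-0.48) and Ctgf (-0.39). Tenascin C was higher than in untreated cells, at 300 against 117 CPM (Tnc log2 ratio 1.35, 0.64 in Xist-only cells), and Postn was at 7028 against 5035 CPM (0.48, 0.20).

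Myofibroblast transcripts gave opposite answers over all cells and within Xist-only cells. Acta2 was at 2127 against 1321 CPM over all fibroblasts (log2 ratio 0.69), yet at -0.62 in Xist-only cells. The contractile list had a median of 0.24 over all fibroblasts (28 of 38 genes above 0, Cnn1 at 1.67, Myh11 at 1.64, Actg2 at 1.39) and of -0.15 in Xist-only cells (8 of 38 above 0). A UMI of Acta2 was seen in 54.8% of thinned fibroblasts with cilengitide and 50.3% without (80.2% and 79.5% unthinned), against 8.23% and 3.58% of macrophages. Within the cilengitide library itself, Y-only fibroblasts exceeded Xist-only fibroblasts by 1.69 in Acta2 and by 0.52 in the contractile median. These Y-only and Xist-only fibroblasts had median depths of 14239.5 and 9555 UMIs, and the values were not thinned. Col5a1 was likewise higher over all cells (377 against 302 CPM, 0.32) but not in Xist-only cells (-0.045). Col5a2 (-0.0044, -0.19), Col5a3 (-0.20, 0.18), Col1a1 (0.25, -0.014), Col1a2 (0.30, 0.10) and Col3a1 (0.14, 0.27) differed by small amounts.

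Among lists in fibroblasts, integrin subunits (median -0.16, -0.17 in Xist-only cells, but -0.043 with classes from own clusters, -0.0033 with a minimum of 1 UMI and -0.48 with CKO of the first table as the reference), angiogenesis genes (-0.39, -0.28, Dll4 at -2.10, Flt1 at -1.42), non-collagen matrix proteins (0.14, 0.19, Tgfbi at 0.83, Thbs2 at 0.71), fibrillar collagens (0.13, 0.14), late scar genes (0.14, 0.19, Cpz at 0.80) and focal adhesion genes (0.13, 0.13, Tes at 1.16) kept their direction in Xist-only cells, though with CKO of the first table as the reference the focal adhesion median was -0.016 and that of non-collagen matrix proteins 0.38, and in thinned cells that of fibrillar collagens was 0.071. Endothelial markers fell alongside the angiogenesis list, from 0.0135% of fibroblast UMIs (0.0131 to 0.0139%) to 0.0103% with cilengitide (0.00999 to 0.0105%). Resting fibroblast genes (-0.10, 0.45, Mgp at -0.93, Gpc3 at -0.94), other collagens (-0.26, 0.048, Col4a1 at -0.82), matrix proteases (-0.028, 0.13, Adam12 at 0.80), glycolysis (0.18, -0.021, Gapdh at 0.54), oxidative phosphorylation (0.033, -0.048, Uqcrc1 at 0.40), collagen processing (0.090, -0.027, P4ha2 at 0.55), endoplasmic reticulum folding (0.033, -0.053, Pdia4 at -0.43), TGF-beta genes (-0.021, 0.018, Smad7 at -0.62), recruited monocyte genes (0.14, -0.24, Ly6c2 at 1.54) and cell cycle genes (0.016, -0.36, Top2a at -0.49) did not. The interferon (0.13, 0.0063, Ifit1 at 0.75), inflammatory (0.12, 0.017, Ccl8 at 1.55) and immediate early stress lists (-0.020, -0.029, Egr2 at -0.54) were at 0 or near it in Xist-only cells. Class II genes (0.69, 0.37, Cd74 at 0.86), resident macrophage genes (0.53, 0.61, Pf4 at 1.37) and phagocytic genes (0.19, 0.20, Gpnmb at 1.13) were higher beside a macrophage marker share of 0.378% of fibroblast UMIs against 0.303% in CKO untreated. With CKO of the first table as the reference the class II median was -0.59 and the interferon median -0.091.

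**Figure D4:**
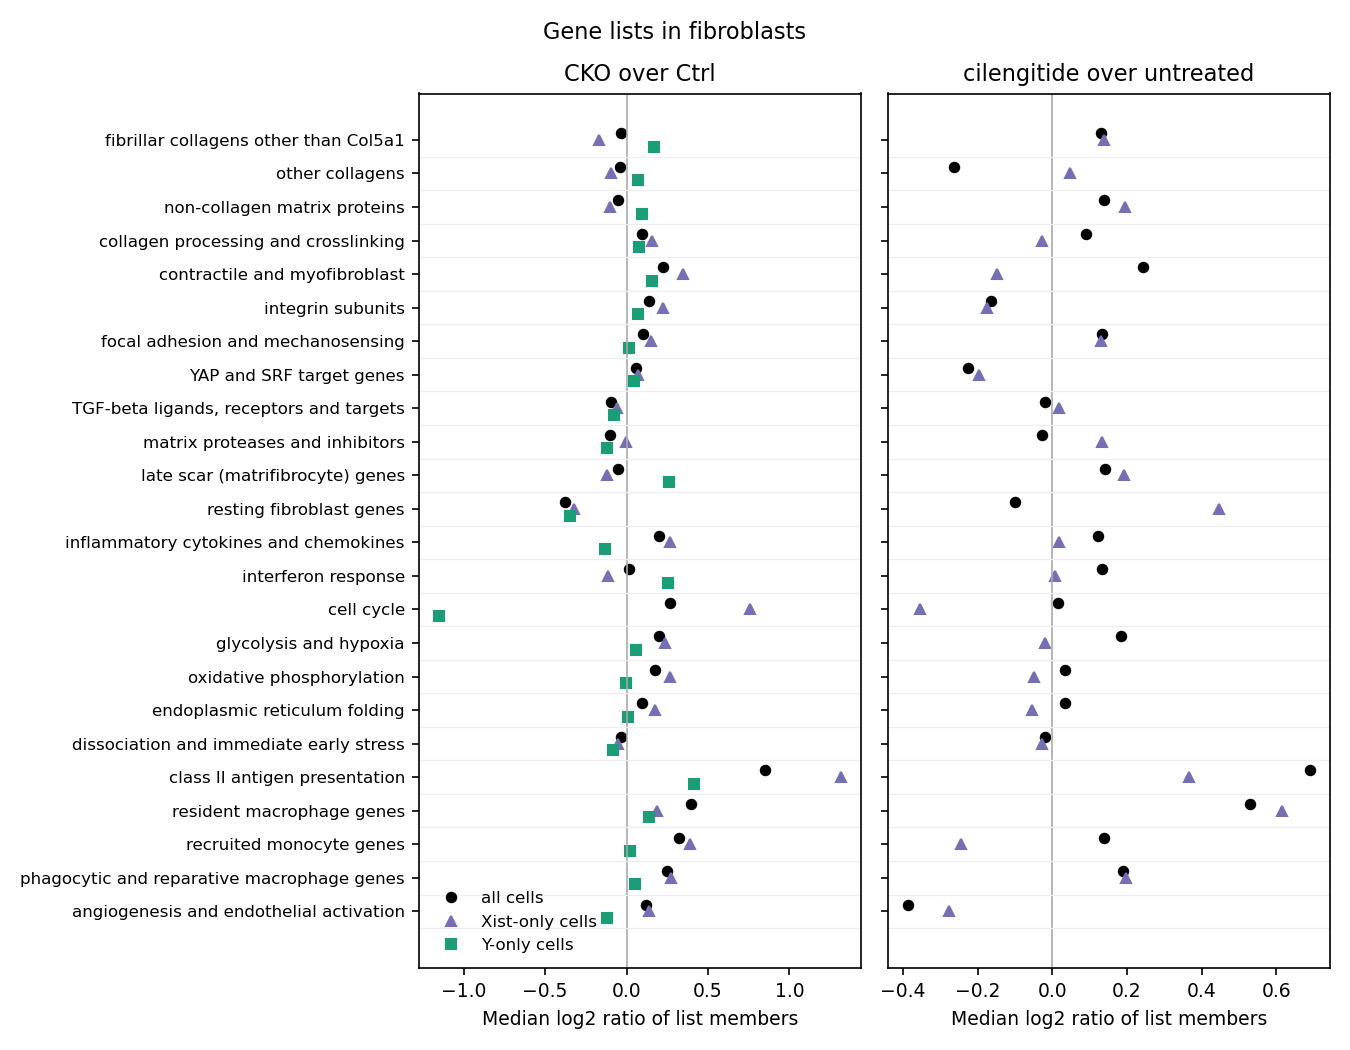
Median log2 ratio of the measured members (x axis) of 24 gene lists (y axis) in fibroblasts, CKO over Ctrl on the left and cilengitide over untreated on the right, over all cells, Xist-only cells and Y-only cells. Contractile genes lie at 0.23, 0.35 and 0.16 on the left, and at 0.24 and -0.15 on the right.

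The fibroblast genes farthest above untreated were the chaperone clusterin (Clu, 166 against 40.7 CPM, log2 ratio 2.03, 1.69 in Xist-only cells), Uts2r (2.39, 2.54), tenascin N (Tnn, 1.88, 0.91), Lrrc15, a marker of activated fibroblasts (1.61, 0.62), C1qtnf3 (1.46, 0.74), Gap43 (1.75, 1.97), Tnc, Far2os1 (1.79) and Npl (1.34, 1.52). Clu also led the own cluster of epicardial cells, which the deposited classes counted as fibroblasts. That cluster held 84 cells with cilengitide and 23 without, so these cells may have a part in the Clu difference. Epicardial or mesothelial markers went the other way, at 0.00437% of fibroblast UMIs with cilengitide and 0.00561% without. Egr4 (3.23), Serpinb2 (1.97) and Ddx4 (2.54) were also among the 12, but over 94% of their UMIs with cilengitide lay in 10 cells, and Serpinb2 was at -2.05 in Xist-only cells. The farthest below were the RNA locus AY036118 (44.4 against 205 CPM, -2.21, -1.86), Ttc21a (-1.97, -1.79), the tau gene Mapt (-2.07, -1.75), Syn3 (-1.73, -1.56), Slc10a1 (-2.41, -2.32), Col26a1 (-1.77, -0.98), Sucnr1 (-1.98, -0.84), Slc46a2 (-1.76, -1.50), Mfsd4a (-1.49, -1.45), Tmem200a (-1.52, -1.25), Col9a2 (-1.30, -0.64) and Krt14 (-1.83, -4.25), whose UMIs came from 12 and 11 cells and which was at 3.42 with CKO of the first table as the reference.

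In macrophages, cilengitide went with lower integrin, immediate early and recruited monocyte transcripts. Integrin subunits had a median of -0.38 (-0.48 in Xist-only cells, Itgam at -0.71, Itga4 at -0.70, Itgav at -0.52), immediate early stress genes -0.33 (-0.33, Egr3 at -1.86, Egr1 at -1.03) and recruited monocyte genes -0.39 (-0.90, F10 at -1.08, Chil3 at -0.91). Phagocytic genes were higher (0.21, 0.21), as were class II genes (0.15, 0.48, H2-Aa at 0.38), though their median was -0.076 with CKO of the first table as the reference. The iron exporter Slc40a1 (log2 ratio 1.12, 1.16) and its regulator Spic (1.39, 1.19) were both higher, with Npy (0.96, 0.91) and Cdk5rap1 (1.15, 2.31), as was Bcl2l14 (1.84) over all cells, while the platelet chemokine Ppbp (1.68, -1.46) turned over in Xist-only cells. Interleukin 6 was lower, at 3.69 against 18.3 CPM (Il6 log2 ratio -2.30, -3.29), though its highest level lay in another class. AY036118 was lower here too (-2.12, -1.98). The mast cell protease genes Cpa3 (at least 46.4-fold lower), Tpsb2 (2 against 148 UMIs) and Cma1 (47 against 194 UMIs), and Retnla (6 against 61 UMIs), each came from 10 cells or fewer per library.

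In endothelial cells, YAP and SRF targets (median -0.26, -0.36 in Xist-only cells, Ankrd1 at -1.43), TGF-beta genes (-0.16, -0.20, Smad7 at -0.53) and immediate early stress genes (-0.17, -0.25) were lower, as were the adhesion molecules Sele (-1.59), Selp (-1.15) and Vcam1 (-0.64) within the angiogenesis and activation list (-0.085, -0.11). With CKO of the first table as the reference the YAP and SRF median was 0.064, and with every cell thinned to 2000 UMIs the stress median was 0.0079. AY036118 (-2.20), Nrg1 (-2.87), the heat shock gene Hspa1b (-2.01), Mapt (-2.36), Bdnf (-1.94) and Tmem108 (-2.02) were lowest, and all but Mapt, too sparse there, stayed below 0 in Xist-only cells. The chemokine Cxcl9 (1.21, 1.83), Amd2 (1.19, 1.21), Ifit1 (0.98, 0.55), Ms4a6d (0.91, 0.28) and Htra3 (1.03, 1.27) were higher in both, and Nts was higher over all cells only (1.25, -0.77), and was at -0.86 with CKO of the first table as the reference. Macrophage markers rose from 0.319% to 0.477% of endothelial UMIs and fibroblast markers from 0.422% to 0.521%, so genes of those cells such as Ms4a6d and Htra3 may come from their RNA.

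Cell composition also differed with cilengitide, as a ratio most in lymphocytes, though by how much depended on the reference. B cells were 2.68% of the cilengitide library (2.40 to 2.99%) and 0.103% of CKO untreated (7 cells, 0.0415 to 0.212%), and T cells 2.50% against 0.398%. Their differences of 2.58 and 2.10 points were 1.55 and 2.20 in Xist-only cells, and 2.13 and 0.869 with CKO of the first table as the reference. Neutrophils were 1.78% against 1.09%, fibroblasts 36.5% (35.6 to 37.3%) against 39.9% (38.8 to 41.1%), endothelial cells 5.20% against 6.29%, and macrophages 50% against 50.9%, while smooth muscle cells were 1.33% in both. The fibroblast, macrophage, endothelial and neutrophil differences were -3.47, -0.807, -1.09 and 0.688 points. In Xist-only cells they were 0.357, -4.46, 0.171 and -0.197. With CKO of the first table as the reference they were 17.6, -18.3, 0.585 and -1.65. Of neutrophils, 35.1% were Xist-only in CKO untreated (26 of 74) and 3.35% in CKO cilengitide (7 of 209). The Xist-only shares therefore mix sex and detection of Xist with composition.

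Whether genes that were higher in CKO than in Ctrl were lower with cilengitide depended on the class and on the cells used. No Y-only value exists, since CKO untreated had no Y-only cells, so dependence on sex was not tested. In fibroblasts, across 11821 genes measured in both comparisons, which are not independent replicates, the log2 ratios had a Pearson correlation of 0.121 and a Spearman correlation of 0.185, and 43.6% of genes had opposite signs. In Xist-only fibroblasts the Pearson correlation was -0.0971 over 11224 genes. In macrophages it was -0.0948 over 11366 genes, with 55.5% of opposite sign, and -0.254 in Xist-only cells, and in endothelial cells it was 0.193 over 7740 genes. Between Xist-only and Y-only fibroblasts the CKO over Ctrl ratios themselves correlated at 0.0542 over 8357 genes. Beyond counting error, the standard deviation of the log2 ratios over 4996 fibroblast genes was 0.215 for CKO over Ctrl and 0.233 for cilengitide over untreated in Xist-only cells, and 0.254, 0.199 and 0.264 for Y-only over Xist-only cells within Ctrl, CKO and CKO cilengitide. Over 6553 macrophage genes these values were 0.205 and 0.313, and 0.191, 0.184 and 0.219. For CKO over Ctrl in Y-only cells they were 0.246 in fibroblasts and 0.157 in macrophages.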

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

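The tests by sex of the cells, by smooth muscle transcripts, by Col5a1 in macrophages, by where the Prm1 UMIs lie and by the knockout libraries were chosen after the result was seen.

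Contractile genes were higher in fibroblasts with cilengitide over all cells but lower in Xist-only fibroblasts, with a median log2 ratio of -0.15 (-0.18 to -0.10). This is consistent with the other makeup of animals by sex as a source of the pooled difference, since the untreated library had 0 Y-only fibroblasts. Smooth muscle cells or their RNA are argued against as the whole source. The summed excess of the list would need 8.38% of fibroblast UMIs (8.25 to 8.51%) to come from them, while their 20 most abundant transcripts outside the list, at 10 times the untreated fibroblast level or more, allow a median of -0.32% (-0.40 to -0.079%). Rgs5, at 2928 CPM in smooth muscle cells, stood at 27.5 against 24.9 CPM in fibroblasts. A small part stays open, since the members went both ways. With cells thinned the median was 0.14 (0.11 to 0.23) around the bound of 0.12 set for depth, so depth stays open in part. Thinning was run over all fibroblasts only. Xist-only fibroblasts had a median of 9555 UMIs with cilengitide and 14535 without, so depth stays open for their median of -0.15 too. The treatment cannot be told apart from sex in the pooled values, and animals may differ in other ways that were not tested.

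Matrix genes were higher in CKO macrophages. The 13 fibroblast markers were also higher in neutrophils, T cells and B cells pooled (median 0.82, 0.51 to 1.07), which is consistent with free RNA of fibroblasts. Without the 5% of macrophages richest in these markers the median was 0.94 (0.77 to 1.09), against a bound of 0.42, which argues against a few doublets. Col5a1 lay -0.96 (-1.43 to -0.21) from the median of the markers in macrophages, an interval too wide to say whether macrophages made part of this RNA themselves. In fibroblasts Col5a1 was lower by more than this, while the markers made up 3.94% of UMIs in CKO and 4.45% in Ctrl. Free RNA of fibroblasts was therefore not shown to be the only source. The fibroblast share itself was lower in CKO, and why its free RNA might be higher was not tested.

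Prm1 and Gpt2 were high in fibroblasts of each CKO library and low in Ctrl. Male germ cells are argued against by Tnp2 and Odf1, whose UMIs came to 0.0895% of those of Prm1 (Prm2 and Tnp1 are absent from the tables), and free RNA by 94.1% of 1187 Prm1 UMIs lying in fibroblasts, which held 45.4% of all UMIs. A change shared by the region around Gpt2 is argued against by the 32 measured genes within 1 Mb, with a median of 0.014 (-0.025 to 0.048). Their log2 ratios ran from -0.38 to 1.23, so a change of single genes near Gpt2 stays open. The lowest Prm1 level in knockout fibroblasts was 9.28 CPM. The knockout, or a construct with a piece of Prm1, may be the source, which cannot be told apart without reads and without a Ctrl animal carrying the construct.

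The remaining results moved one way in Xist-only and the other way in Y-only cells for CKO over Ctrl, and the difference between the kinds of cells was not tested. In fibroblasts the medians were -0.17 and 0.17 for fibrillar collagens, -0.10 and 0.092 for matrix proteins, -0.12 and 0.26 for late scar genes, -0.12 and 0.25 for interferon response, and 0.76 and -1.15 for cell cycle. In macrophages they were -0.12 and 0.16 for inflammatory cytokines, -0.21 and 0.39 for interferon response, 0.17 and -0.30 for cell cycle, -0.066 and 0.20 for immediate early stress, and -0.19 and 0.51 for class II genes. Single genes in fibroblasts were Col1a1 (-0.17 and 0.15), Col1a2 (-0.085 and 0.19), Col3a1 (-0.36 and 0.040), Postn (-0.068 and 0.61) and Itgav (0.13 and -0.35).

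Genes left out of the ranking also differed between libraries. Over all cells, haemoglobin reached 45.2 CPM of Hbb-bs and 7.65 of Hba-a1 in CKO, against 17.9 and 1.48 in Ctrl, and 68.9 and 19.6 CPM in CKO untreated, against 1.24 and 0.465 in CKO cilengitide. Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d reached 40.2, 32.6, 9.58 and 6.06 CPM in CKO cilengitide, against 0, 0, 0 and 0.0735 in CKO untreated.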

How the results depend on the processing

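The splits by Xist and Y-linked UMIs, the limit of 0.2 on the Scrublet score and the lists without members of low level were chosen after the data had been seen, and the other alternatives before the data were examined. No paired analysis was possible because each group had 1 library. A result counted as called when its interval left out 0, or for a list when its median lay outside the middle 95% of random lists. Of 116 called gene ratios, 96 never changed direction under any alternative in which they were measured, among them Col5a1, Acta2, Gpt2 and Prm1 in fibroblasts for CKO over Ctrl. Most of these genes were named because their interval bound lay far from 0 in these same libraries. For those, being called was fixed by the choice, and keeping direction was made likely, so the count does not describe genes at large. Of 89 called list medians 49 never changed direction, and of 10 called share differences 2. Scaling by the trimmed mean of M values, by median of ratios or by a total without the 50 most abundant genes turned no called gene ratio or list median, and shares do not depend on scaling. The largest shift of all ratios by scaling was -0.075 (log2). Called results that changed direction, and main results that moved beyond their counting interval, follow by alternative, and the cause was not tested except where one is named. Values near 0 rest on small differences.

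In Xist-only cells, CKO over Ctrl had log2 ratios of -0.068 for Postn, -0.17 for fibrillar collagens, -0.10 for non-collagen matrix proteins, 0.35 for contractile genes and 0.23 for integrin subunits in fibroblasts, 0.17 for cell cycle in macrophages, -0.56 for Hmox1 in endothelial cells. In Xist-only cells, its share difference in points was -9.56 for fibroblast and 15.5 for macrophage. In Xist-only cells, cilengitide over untreated had log2 ratios of -2.05 for Serpinb2, -0.045 for Col5a1, 0.18 for Col5a3, -0.014 for Col1a1, -0.62 for Acta2, 0.048 for other collagens, 0.19 for non-collagen matrix proteins, -0.15 for contractile genes, 0.45 for resting fibroblast genes, -0.021 for glycolysis and -0.24 for recruited monocyte genes in fibroblasts, -1.46 for Ppbp, -0.18 for resting fibroblast genes, -0.24 for interferon response and -0.46 for cell cycle in macrophages, -0.77 for Nts in endothelial cells. In Xist-only cells, its share difference in points was 0.171 for endothelial, 0.357 for fibroblast, -4.46 for macrophage and -0.197 for neutrophil. In Xist-only cells, the comparisons correlated at -0.0971 across genes.

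In Y-only cells, CKO over Ctrl had log2 ratios of -1.71 for Col5a1, 0.15 for Col1a1, 0.19 for Col1a2, 0.040 for Col3a1, 0.17 for fibrillar collagens, 0.092 for non-collagen matrix proteins, 0.16 for contractile genes, 0.070 for integrin subunits, -0.13 for inflammatory cytokines, -1.15 for cell cycle and -0.0013 for oxidative phosphorylation in fibroblasts, -0.17 for YAP and SRF target genes and -0.049 for glycolysis in macrophages, 0.37 for interferon response, -0.063 for oxidative phosphorylation, -0.060 for endoplasmic reticulum folding and 0.49 for immediate early stress genes in endothelial cells. In Y-only cells, its share difference in points was 0.10 for B cell, 0.0595 for endothelial and -12.2 for fibroblast.

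When the untreated CKO libraries of both tables traded places, CKO over Ctrl had log2 ratios of -1.62 for Col5a1, 0.21 for Mmp3, 0.33 for Col1a2, -0.52 for Itgb1, -0.090 for fibrillar collagens, 0.12 for non-collagen matrix proteins, 0.0021 for integrin subunits, 0.031 for TGF-beta genes, -0.035 for endoplasmic reticulum folding and -0.54 for class II genes in fibroblasts, 0.15 for Pdpn and 0.16 for phagocytic genes in macrophages, -0.74 for Nts, -0.68 for Ccl2, -0.99 for Nrg1, -0.26 for inflammatory cytokines and -0.11 for endoplasmic reticulum folding in endothelial cells. With that exchange, its share difference in points was 13.6 for fibroblast, -6.63 for macrophage and 0.0275 for smooth muscle. With that exchange, cilengitide over untreated had log2 ratios of 3.42 for Krt14, 0.58 for Col5a1, 0.38 for non-collagen matrix proteins, -0.48 for integrin subunits, -0.016 for focal adhesion genes, 0.079 for resting fibroblast genes, -0.091 for interferon response and -0.59 for class II genes in fibroblasts, -0.19 for interferon response and -0.076 for class II genes in macrophages, -0.86 for Nts and 0.064 for YAP and SRF target genes in endothelial cells. With that exchange, its share difference in points was 0.585 for endothelial, 17.6 for fibroblast, -18.3 for macrophage and -1.65 for neutrophil.

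With every cell thinned to 2000 UMIs, CKO over Ctrl had log2 ratios of 0.017 for Col1a2 in fibroblasts, 0.020 for cell cycle in macrophages. In thinned cells, cilengitide over untreated had log2 ratios of 0.27 for Col5a1, 0.071 for fibrillar collagens, 0.16 for non-collagen matrix proteins, 0.14 for contractile genes and 0.067 for resting fibroblast genes in fibroblasts, -0.054 for collagen processing and -0.066 for cell cycle in macrophages, -0.015 for inflammatory cytokines and 0.0079 for immediate early stress genes in endothelial cells. In thinned cells, the comparisons correlated at 0.139 across genes.

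When each cell weighed the same, CKO over Ctrl had log2 ratios of -1.79 for Col5a1, 0.060 for Col1a2, -0.0074 for non-collagen matrix proteins and 0.23 for integrin subunits in fibroblasts, 0.050 for cell cycle in macrophages. When each cell weighed the same, cilengitide over untreated had log2 ratios of 0.29 for Col5a1, 0.093 for fibrillar collagens, 0.15 for non-collagen matrix proteins and 0.024 for resting fibroblast genes in fibroblasts, -0.051 for cell cycle in macrophages.

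Without list members whose level was under 0.1 of that in another class, CKO over Ctrl had log2 ratios of 0.077 for integrin subunits and -0.038 for inflammatory cytokines in fibroblasts, -0.088 for resting fibroblast genes and -0.096 for angiogenesis genes in macrophages, -0.030 for inflammatory cytokines in endothelial cells. Without those members, cilengitide over untreated had log2 ratios of -0.31 for integrin subunits in fibroblasts, -0.35 for non-collagen matrix proteins, -0.20 for collagen processing, -0.065 for contractile genes and -0.62 for resting fibroblast genes in macrophages, -0.13 for late scar genes in endothelial cells.

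With classes from own clusters, CKO over Ctrl had log2 ratios of -0.54 for Prtn3, -0.0049 for glycolysis and -0.049 for recruited monocyte genes in macrophages. With classes from own clusters, its share difference in points was 0.0748 for B cell and 2.59 for macrophage. With classes from own clusters, cilengitide over untreated had log2 ratios of -0.043 for integrin subunits in fibroblasts.

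In cells with at least 500 genes and under 10% mitochondrial UMIs, CKO over Ctrl had log2 ratios of -1.93 for Col5a1 in fibroblasts. With median of ratios scaling, CKO over Ctrl had log2 ratios of -0.083 for non-collagen matrix proteins and 0.20 for contractile genes in fibroblasts. With totals that left out the 50 most abundant genes, CKO over Ctrl had log2 ratios of -0.082 for non-collagen matrix proteins and 0.20 for contractile genes in fibroblasts. With no minimum above 1 UMI, CKO over Ctrl had log2 ratios of -0.015 for TGF-beta genes in endothelial cells. With no minimum above 1 UMI, cilengitide over untreated had log2 ratios of -0.0033 for integrin subunits in fibroblasts, -0.047 for other collagens in macrophages. Without cells called doublets, cilengitide over untreated had log2 ratios of 0.35 for Col5a1 and 0.15 for non-collagen matrix proteins in fibroblasts. With trimmed mean of M values scaling, cilengitide over untreated had log2 ratios of 0.17 for non-collagen matrix proteins and 0.27 for contractile genes in fibroblasts. Without cells of a Scrublet score above 0.2, cilengitide over untreated had log2 ratios of 0.15 for non-collagen matrix proteins in fibroblasts. At a minimum of 200 UMIs, the comparisons correlated at 0.166 across genes. As a Spearman correlation, the comparisons correlated at 0.185 across genes.

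Results that were not called were 3 gene ratios, 15 list medians and 6 shares, of which 2, 12 and 3 changed sign under some alternative. Those that did so beyond their counting interval follow. For CKO over Ctrl in fibroblasts, Itgav was at 0.13 in Xist-only cells and 0.095 when each cell weighed the same, fibrillar collagens at 0.17 and other collagens at 0.072 in Y-only cells, late scar genes at 0.26 in Y-only cells, 0.28 with the other CKO library and 0.055 in thinned cells, interferon response at -0.12 in Xist-only cells, -0.10 with the other CKO library and -0.040 without cells of a Scrublet score above 0.2, and angiogenesis genes at -0.12 in Y-only cells. Its neutrophil share difference was -2.06 points with the other CKO library, and its T cell difference 1.73 in Y-only cells. For cilengitide over untreated in fibroblasts, the values in Xist-only cells were -0.027 for collagen processing, 0.018 for TGF-beta genes, 0.13 for matrix proteases, -0.36 for cell cycle, -0.048 for oxidative phosphorylation and -0.053 for endoplasmic reticulum folding. With the other CKO library they were 0.020 for Col5a2, 0.072 for TGF-beta genes, 0.17 for matrix proteases and -0.055 for endoplasmic reticulum folding. With trimmed mean of M values scaling they were 0.026 for Col5a2, 0.0094 for TGF-beta genes and 0.010 for immediate early stress genes, with thinned cells 0.011 for TGF-beta genes, without doublets 0.014 and under the score limit 0.013 for Col5a2, and with an equal weight per cell -0.067 for cell cycle.

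Prtn3 and the macrophage share moved with own classes because a cluster of 1159 cells, led by Saa3, Arg1 and Prtn3, stayed unnamed by the marker rule and left the class. With fewer list members or no minimum of UMIs, medians rest on other genes by construction. Epithelial and dendritic classes gave no value with the other CKO library, since the second table has neither. Scrublet marked 4 CKO cells (0.0365%), so in that library the caller has not worked and its removal there tests nothing. At a true 1.5-fold change simulated counts for CKO and Ctrl fibroblasts gave the right direction beyond the counting interval for 84.8% of genes, against 94% for cilengitide and untreated, and at 3-fold for 100% in both. Those rates hold for Poisson counts, without the spread between cells or animals.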

Other observations

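These values were looked up after the macrophage genes of the first comparison had been seen. A cluster of 1159 cells led by Saa3, Arg1, Prtn3, Fcna, Ltc4s, Ccl24 and Prg4 held 1030 macrophages of CKO and 129 of Ctrl. In thinned macrophages, a UMI of Saa3 was seen in 2.41% of Ctrl, 12% of CKO, 15.2% of CKO untreated and 7.05% of CKO cilengitide cells, and one of Prg4 in 0.498%, 4.37%, 5.21% and 2.14%. Several of these genes are known from macrophages of the serous cavities, and no explanation was tested. Gata6, looked up with them, stood at 1.39, 3.23, 4.91 and 2.52 CPM in macrophages of the libraries in that order. In fibroblasts it stood at 92.3, 86.4, 96.6 and 85.2 CPM, so its macrophage level was not separated from free RNA of fibroblasts. Icam2 stood at 9.71, 38.0, 35.7 and 18.1 CPM in macrophages.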
